A study of Homo sapiens with 8 samples.

How the data were processed

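Gene expression was measured in the human colon carcinoma line Caco2 and the human melanoma line WM115. Cells of each line were sorted by flow cytometry with the AC133 antibody, which binds an epitope of CD133, the protein encoded by PROM1. Per the labels, the AC133 high cells were the brightest 10% and the AC133 negative cells were those without staining, with doublets and dead cells gated out. Each line was sorted 2 times, which gave 4 groups of 2 arrays and 8 arrays in all, and the labels call the repeats biological duplicates. The Caco2 cells carried a reporter in which the mouse Melk promoter drives a green fluorescent protein and came from clones of that culture, and the labels do not say which clone entered which sort. Per the labels, 500 ng of RNA was amplified, and 750 ng of labelled product was incubated for 18 h at 58 °C on HumanRef-8 arrays of version 2. The array codes place all 8 arrays on the same slide, so no slide batch separates them.

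The deposited file of each array gives an intensity per probe, the mean bead signal from BeadStudio 3, on a linear scale and with no sign of normalization between arrays. Whether background had been subtracted is not stated, and no value was at or below 0. Each deposited file also gives a detection p-value per probe, which ranks the probe against the negative control probes of that array in steps of 1 in 708. Other columns, per the file headers, give the number of beads per probe and the standard error of the signal over beads. The authors' joint table holds intensity on a linear scale after quantile normalization by the authors, with medians of 60.0 on every array and a rank correlation of 1 with that array's own signal. The files list 22184 probes, of which 19715 carry a gene symbol and 2469 carry none. Current symbols were assigned through the gene number for 19695 of these probes. The files name no genome build, so no positions are given.

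The intensity of each array was background corrected by the normexp method of limma 3.58.1 in R 4.3.3, with the level of the negative controls inferred from the detection p-values and an offset of 16. The 8 arrays were then quantile normalized and taken to log2. A probe was tested where its detection p-value was under 0.05 on both arrays of at least 1 of the 4 groups, which kept 13844 probes for 11214 named genes. Between 11915 and 13144 probes were detected per array. Bead numbers had a median of 41 to 42 per probe, and the standard error over beads had a median of 4.09% to 4.51% of the signal among detected probes. The number of arrays limits the precision of each comparison, and the median standard error of a log2 difference within a line was 0.19.

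A limma model of the 4 group means was fitted to all 8 arrays, so that the groups share an estimate of the spread with 4 residual and 4.35 prior degrees of freedom. It gave AC133 high minus negative in each line, the mean of these differences over the lines, the difference between them, and Caco2 minus WM115. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all probes tested, with a threshold of 0.05. Counts are of probes unless genes are named. The p-values measure the spread between these sorted samples of each line. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so the shared spread carries every test.

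Shifts of 21 gene lists were tested with limma's camera, which compares a list with all other tested genes, at a preset correlation between genes of 0.01 and with adjustment over the 21 lists within a comparison. The test was repeated with a correlation estimated from the arrays. Limma's fry, which asks whether a list's own genes moved without comparing them with other genes, was run beside it. The gene's probe was the tested probe with the highest mean signal. The lists were S phase and DNA replication, G2 and mitosis, replication-dependent histones, cell cycle inhibitors and quiescence, p53 targets, enterocyte differentiation, Wnt targets and intestinal stem cell genes, melanocyte lineage, mesenchymal and extracellular matrix genes, epithelial junctions and keratins, pluripotency, markers used for tumour-initiating cells, immediate early and dissociation response, unfolded protein and amino acid stress response, hypoxia response, cholesterol synthesis, ribosomal proteins, oxidative phosphorylation, protein glycosylation, interferon response, and blood cell markers.

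The lists, the tests, the alternatives and the rule for naming genes were set before the data were examined. Named genes are PROM1 and MELK in every comparison. In each line and in the average over lines, they are also the up to 10 genes per direction with the largest difference among those past the threshold with 1 direction in every sort. Where fewer than 5 passed, the 5 with the smallest p were named, with their adjusted p. For the difference between lines the rule takes up to 5 per direction, for each list up to 4 members with the smallest p in the average, and between the lines 2 enterocyte and 2 melanocyte genes. Genes known only by a locus code count but are not named. Where the dimmer group was not above background on any array, a fold is given as at least N-fold. It was computed against the larger of the probe's own value and the lowest normalized value of a detected probe on that array.

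The high and the negative array of the same sort deviated from their group means together, with a correlation across probes of 0.281 in Caco2 and 0.177 in WM115, so the sort number pairs the arrays. A fit with the sort as replicate block was therefore run as an alternative, and its count or adjusted p is given with each named gene whose call it ended and each count it moved by more than 1.5 times. It estimates a sort effect in each line, which leaves fewer residual degrees of freedom than the 4 of the main fit. A call lost in it may therefore reflect that loss as well as the pairing. The remaining alternatives changed the background correction, its offset, the normalization, the filter on dim probes, the arrays in the fit, the test, array weights, the correlation between genes and the probe chosen per gene, and left out each array in turn. The Caco2 test was checked on simulated data built from these arrays with 200 of 13844 probes shifted. It recovered 48 of 100 probes shifted by 1 log2 unit and 93 of 100 shifted by 2, with 6 false calls. Of 20 runs with no shift, 2 made any call. The simulated noise was independent between probes and arrays and held no pairing by sort, so these runs do not cover its effect on false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.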

Results

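Transcript levels were measured on human bead arrays in AC133 high and AC133 negative cells of Caco2, a colon carcinoma line, and of WM115, a melanoma line, with 2 separately sorted samples per group and 8 arrays in all. The percentage of probes detected above background ran from 53.7% to 59.3% per array. The median signal ran from 49.5 to 58.8 intensity units over a mean background of 37.1 to 39.9 units.

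PROM1, which encodes the protein that carries the AC133 epitope, was far higher in the AC133 high cells of both lines. In Caco2 its normalized log2 signal was 11.03 ± 0.12 (SD, n = 2) in the high cells and 6.86 ± 0.29 in the negative cells, a difference of 18.1-fold. In WM115 it was 9.57 ± 0.04 in the high cells and 5.97 ± 0.35 in the negative cells, a difference of 12.1-fold. The limma adjusted p was 4.1e-04 in Caco2 and 6.9e-04 in WM115, and all 4 sorts had the higher signal in the high cells. The PROM1 differences of the lines were 0.58 log2 units apart, with an adjusted p of 0.926, and 0.33 to 0.83 apart over the alternatives. MELK, a mitotic kinase gene whose mouse counterpart gave the promoter of the reporter in the Caco2 cells, differed by 0.22 log2 units in Caco2 and by 0.17 in WM115, with adjusted p of 0.923 and 1.

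**Figure D1:**
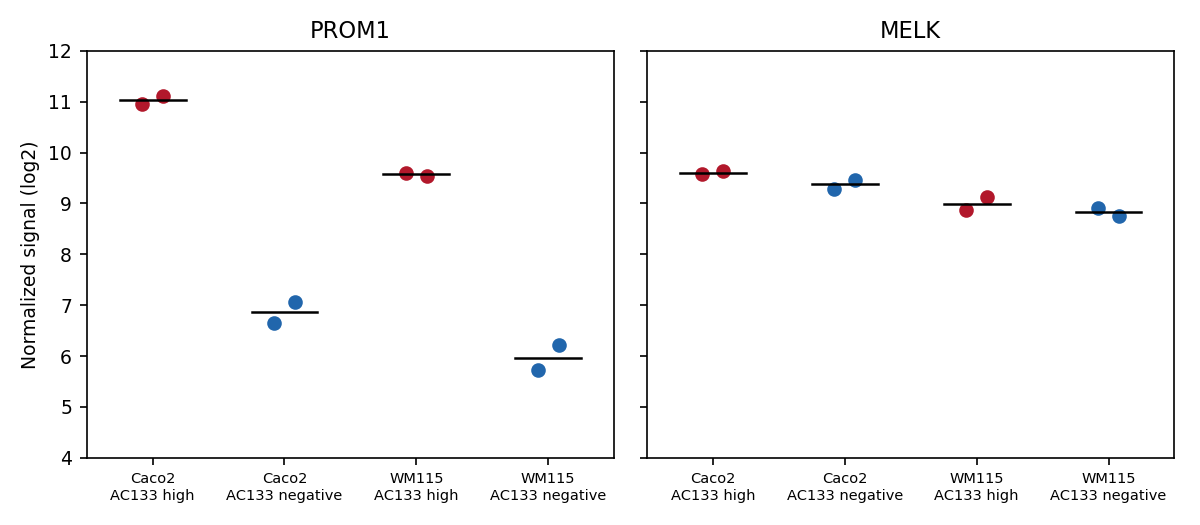
Normalized log2 signal of PROM1 and MELK on each of the 8 arrays (points, AC133 high in red and AC133 negative in blue), with the mean of each group of 2 arrays as a line. PROM1 was 18.1-fold higher in the high cells of Caco2 and 12.1-fold higher in those of WM115. The MELK group means of high and negative cells lie 0.22 log2 units apart in Caco2 and 0.17 in WM115. In sort 1 of WM115 the high cells had the lower MELK signal.

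The first comparison asked which transcripts differ between AC133 high and negative Caco2 cells. After PROM1 the largest rises were in AFP and ALB. AFP, the fetal serum protein alpha-fetoprotein, rose 9.90-fold (SE 0.25 log2 units, n = 2 per group), ALB, serum albumin, rose 8.19-fold, and FGB, the fibrinogen beta chain, rose by 2.10 log2 units. SELENOP, a secreted selenium carrier, rose by 2.52 log2 units. SPTSSB, a subunit of the first enzyme of sphingolipid synthesis, rose at least 5.27-fold from a level not above background. GJA1, the gap junction protein connexin 43, rose by 2.48 log2 units, the collagen gene COL5A2 by 2.15, and SCGN, a calcium-binding protein of endocrine cells, by 1.92. VCAN, the matrix proteoglycan versican, rose at least 3.31-fold.

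Genes lower in the AC133 high Caco2 cells were led by EGFLAM, a matrix protein, at least 7.61-fold, and SMOC2, a secreted protein expressed in intestinal stem cells, with a log2 difference of -3.06 (SE 0.30). GPR83, a G protein-coupled receptor gene, fell by 2.95 log2 units and EDN3, endothelin 3, fell at least 6.62-fold. NKD1 and NOTUM, which both encode inhibitors of Wnt signalling, fell by 1.74 and by 1.35 log2 units. CYP26A1, which degrades retinoic acid, had a log2 difference of -1.36, although a second probe of the gene gave -0.10. PGM5 fell by 2.11 log2 units on its named probe and differed by -0.36 on another, and MYBPH, a myosin-binding protein gene, fell by 1.68. The ZAP70 probe fell by 2.68 log2 units, but the other 2 probes of this kinase gene gave -0.26 and -0.68 and did not pass. ZAP70, CYP26A1 and NOTUM were detected on 1 of the 2 high arrays, so background limits the size of their falls. Paired by sort, EGFLAM, CYP26A1 and MYBPH missed the threshold, with adjusted p of 0.055, 0.065 and 0.111.

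The enterocyte differentiation list rose together in the AC133 high Caco2 cells. Of its 25 measured genes 23 had a positive difference, with a mean of 0.65 log2 units and shifts of 0.72 and 0.57 in the sorts. Adjusted over the list alone 13 genes rose and none fell, and over all genes 4 rose: MEP1A, a brush border protease, by 1.65 log2 units, DPP4, a brush border peptidase, by 1.21, CEACAM6, an adhesion protein, by 1.74, and CEACAM1, another of its family, by 1.73. A second CEACAM1 probe gave 0.02. Camera gave the list an adjusted p of 1.1e-15, and with an estimated correlation a p of 0.0082, which became an adjusted p of 0.173 over the 21 lists. Fry gave it a p of 0.0022 and an adjusted p of 0.046. By fry no other list passed in Caco2, and none passed in WM115, the average or the difference between lines. Over the 3 members detected on all 8 arrays the shift was 0.75, with an adjusted p of 0.069.

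The list of Wnt targets and intestinal stem cell genes fell in the AC133 high Caco2 cells, with 14 of 21 genes negative, a mean of -0.48 log2 units, and shifts of -0.60 and -0.36 in the sorts. Adjusted over the list alone 7 genes fell, and over all genes SMOC2, NKD1 and NOTUM fell. CD44, a hyaluronan receptor, differed by -0.88 log2 units with an adjusted p of 0.370, and its second probe by -0.39 (0.648). The adjusted p of the list was 7.4e-05, and its p was 0.146 with an estimated correlation. The shift was -0.29 without the negative array of sort 1. Over the 7 members detected on all 8 arrays it was -0.091, with an adjusted p of 0.873. Among markers used for tumour-initiating cells, a list that holds PROM1 itself, ABCB1, a drug efflux pump, rose by 1.71 log2 units, and CXCR4, a chemokine receptor, fell by 1.13. That list had a mean shift of 0.25 and an adjusted p of 0.288. CLDN1, a tight junction protein, rose by 1.14 log2 units and VIM, vimentin, by 1.03, but the epithelial junction list shifted by 0.01 and the mesenchymal list by 0.11, with adjusted p of 0.997 and 0.463. Paired by sort, CLDN1, VIM and CXCR4 missed the threshold, with adjusted p of 0.055, 0.074 and 0.077.

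In all, limma called 107 probes in Caco2, 78 higher and 29 lower, for 71 and 25 named genes. Paired by sort as a replicate block, the fit called 56 probes, 52 of them shared with the 107. The count depends on the arrays in the fit and on the scaling. It was 1 with the 4 Caco2 arrays alone, a fit without the spread shared with WM115, and it fell with any 1 array left out. With median scaling of all 8 arrays it was 41 (35 higher and 6 lower). Named genes kept their direction, but VIM lost its call under 14 of 17 alternatives, CEACAM1 under 12 of 17 and PGM5 under 10 of 17. MYBPH lost it under 13 of 16, CEACAM6 under 10 of 16, CYP26A1 and CXCR4 under 9 of 16, and EGFLAM, DPP4 and CLDN1 under 8 of 16.

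**Figure D2:**
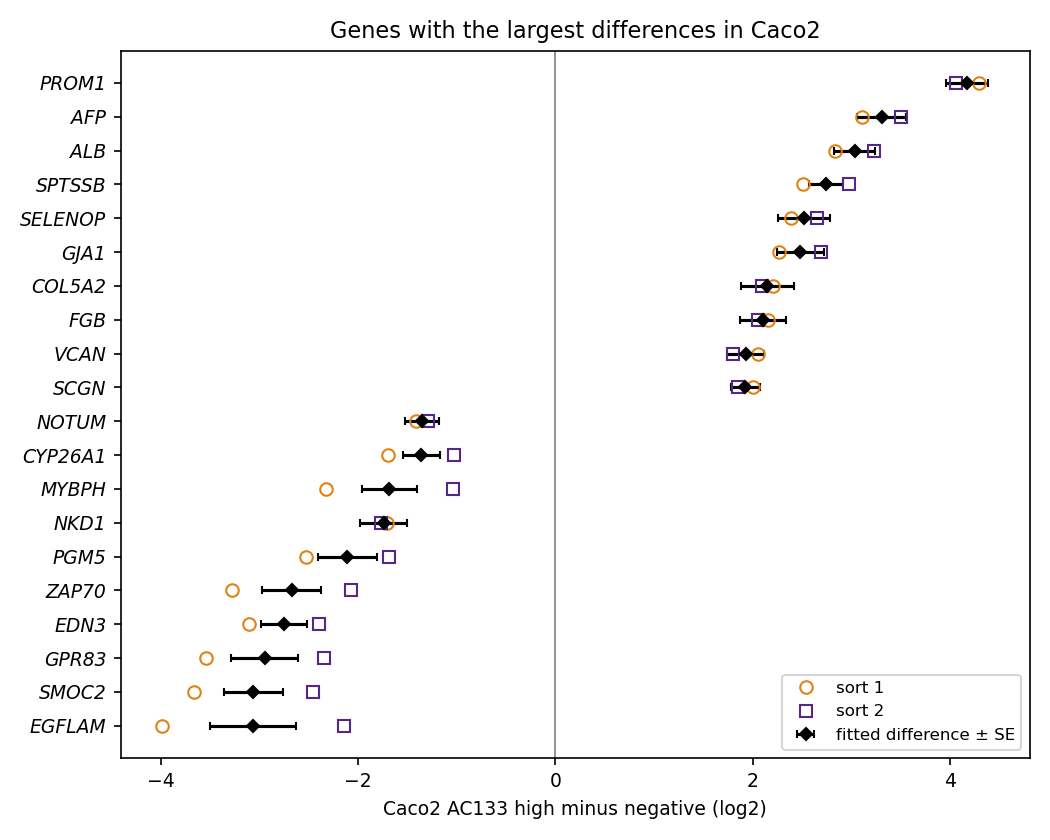
Difference between AC133 high and negative Caco2 cells (log2) for the 10 genes with the largest rise and the 10 with the largest fall past the threshold. Genes known only by a locus code are left out, also where their fall was larger. Diamonds with bars are the fitted difference ± SE, circles and squares are the differences within sort 1 and sort 2, and every gene kept its direction in both sorts, with PROM1 at 4.18 and EGFLAM at -3.07.

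In WM115 the same comparison called CD36, a receptor for fatty acids and thrombospondin, besides PROM1. CD36 fell by 3.93 log2 units in the AC133 high cells (SE 0.26, n = 2 per group) on a probe detected on 1 of the 2 high arrays, so that the size of this fall is limited by background. Its second probe, detected on all 4 arrays, fell by 3.00 log2 units, and the adjusted p were 9.6e-04 and 5.5e-04. Both probes were lower in the high cells in 2 of 2 sorts. These were the 3 probes past the threshold, 1 higher and 2 lower, and 642 probes had an unadjusted p under 0.05 where chance gives 692. Of the genes with the next smallest p, the protease inhibitor gene CST2 differed by 1.55 log2 units, PASD1 by 1.14, HTN1, detected on 1 of the 2 negative arrays, by 1.04 and RNF144B by 1.03, each with an adjusted p of 0.147. On the lower side LPL, lipoprotein lipase, differed by -1.28 (adjusted p 0.147), the cytokine gene IL24 by -1.97 and ACTA2, smooth muscle actin, by -1.38 (each 0.159), and CAMK2N1, a kinase inhibitor, by -1.49 (0.214). A second IL24 probe gave -0.94 (adjusted p 0.474).

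The AC133 negative array of WM115 sort 2 stood apart from the rest. On it 175 probes were more than 2-fold above and 37 more than 2-fold below each of the other 3 WM115 arrays, where the other 7 arrays had 0 to 18 above and 0 to 49 below within their line. The probes furthest above, chosen after their values were seen, were of CCL5 and CXCL8, which encode chemokines, at 5.65 and 5.37 log2 units over the mean of the other 3, and of THBS1, thrombospondin 1, at 5.00. Without the other negative array, that of sort 1, the WM115 count rose from 3 to 249. Without the array that stood apart it was 4.

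**Figure D3:**
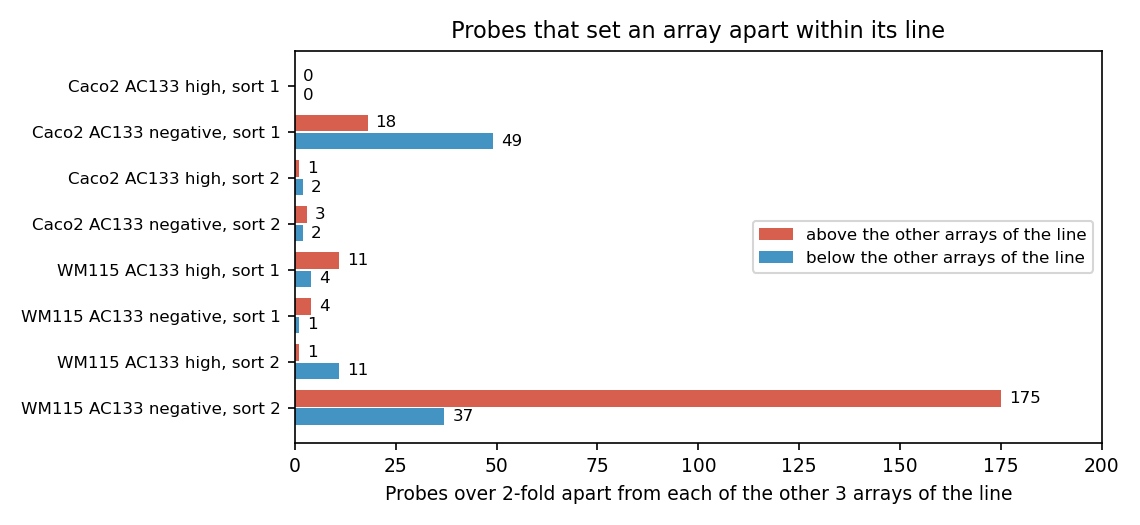
Number of probes on each of the 8 arrays that lie more than 2-fold above (red) or below (blue) each of the other 3 arrays of the same line. The WM115 AC133 negative array of sort 2 had 175 above and 37 below, and the Caco2 AC133 negative array of sort 1 had 18 above and 49 below.

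The mesenchymal and extracellular matrix list fell in the AC133 high WM115 cells, by a mean of 0.83 log2 units. Of its 20 measured genes 16 had a negative difference, 5 fell adjusted over the list alone, and none passed over all genes. Its shift was -0.26 in sort 1 and -1.39 in sort 2, the sort of the array that stood apart, and -0.21 without that array, against -1.44 without the other negative array. S100A4, a calcium-binding protein of motile cells, differed by -2.68 log2 units (adjusted p 0.214) and CDH2, N-cadherin, by -1.34 (0.648). Over the alternatives S100A4 ran from -3.57 to -1.78 and CDH2 from -2.01 to -0.67. The list had an adjusted p of 1.1e-10 and a p of 0.063 with an estimated correlation. With that correlation no list called in either line, in the average or in the difference between lines passed after adjustment over the lists.

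Immediate early and dissociation response genes also fell in WM115, by a mean of 0.29 log2 units, with 22 of 28 negative, and an adjusted p of 1.8e-04. With an estimated correlation the p was 0.027, which became an adjusted p of 0.353, and the call was lost. They shifted by -0.13 and -0.45 in the sorts and by -0.17 without the array that stood apart. The interferon response list shifted by -0.33 (adjusted p 0.045, p 0.483 with an estimated correlation), but by 0.19 in sort 1 and -0.84 in sort 2, was 0.28, past the threshold, without the array that stood apart, and was -0.93 without the other negative array. Its call was also lost without the high array of sort 1, at -0.23, and without any 1 of the 4 Caco2 arrays, as well as over probes detected on all 8 arrays (adjusted p 0.053). The melanocyte lineage list rose by 0.17 (adjusted p 0.029, p 0.350 with an estimated correlation), with -0.03 in sort 1 and 0.36 in sort 2, was -0.09 without that array and 0.42 without the other negative array, and lost its call, at 0.10, without the high array of sort 1. The hypoxia response list rose by 0.17 (adjusted p 0.029, p 0.315 with an estimated correlation), with 0.43 and -0.08 in the sorts, was -0.13 without the high array of sort 1 and 0.47 without that of sort 2, and lost its call without either negative array, at 0.22 and 0.13. Without a filter on dim probes the melanocyte, hypoxia and interferon calls were lost, with adjusted p of 0.054, 0.054 and 0.055, and with the 4 WM115 arrays alone those of melanocyte and interferon genes, with 0.055 and 0.166. No single gene of these 4 lists passed over all genes, and adjusted over the list alone 1 did, the interferon-induced nuclease gene ISG20, at 1.15 log2 units.

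The title of the study names the cell cycle, and a pair of lists was fixed for its phases. Genes of G2 and mitosis rose in the AC133 high WM115 cells, with 62 of 64 positive, a mean of 0.29 log2 units, and shifts of 0.35 and 0.24 in the sorts. HMMR, a spindle protein, differed by 0.63 log2 units, the centromere histone gene CENPA by 0.65 and the cyclin gene CCNA2 by 0.36. Over the alternatives CENPA ran from 0.37 to 0.94. No gene passed alone, over the list or over all genes. The adjusted p of the list was 4.5e-15, its p was 0.034 with an estimated correlation, and that became an adjusted p of 0.353. Genes of S phase and DNA replication fell by a mean of 0.10 log2 units, with 32 of 49 negative (adjusted p 0.029, p 0.429 with an estimated correlation), but shifted by -0.24 and 0.04 in the sorts and by 0.07 without the high array of sort 1 and -0.27 without that of sort 2, and lost the call without either negative array, at -0.13 and -0.07.

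In Caco2 neither list passed with all arrays. Genes of G2 and mitosis shifted by 0.07 log2 units with 39 of 64 positive (adjusted p 0.176), and without the negative array of sort 1 by 0.16, past the threshold, and without that of sort 2 by -0.01. Genes of S phase shifted by -0.12 with 33 of 49 negative (adjusted p 0.068), and passed without either WM115 high array (0.043 each), with the 4 Caco2 arrays alone (0.042) and without a filter on dim probes (0.040). The difference between lines in the G2 and mitosis shift was -0.22 log2 units, with an adjusted p of 2.7e-04 and a p of 0.187 with an estimated correlation. It was -0.14 without the Caco2 negative array of sort 1 and -0.13 without the WM115 negative array of sort 1, and the call was lost in both. Replication-dependent histones shifted by -0.19 in Caco2 and -0.15 in WM115, with adjusted p of 0.060 and 0.205. Within sorts 1 and 2 they shifted by -0.048 and -0.34 in Caco2 and by 0.098 and -0.39 in WM115. Cell cycle inhibitors and quiescence genes shifted by -0.03 in both lines, and in WM115 their median of 0.16 had the opposite sign.

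**Figure D4:**
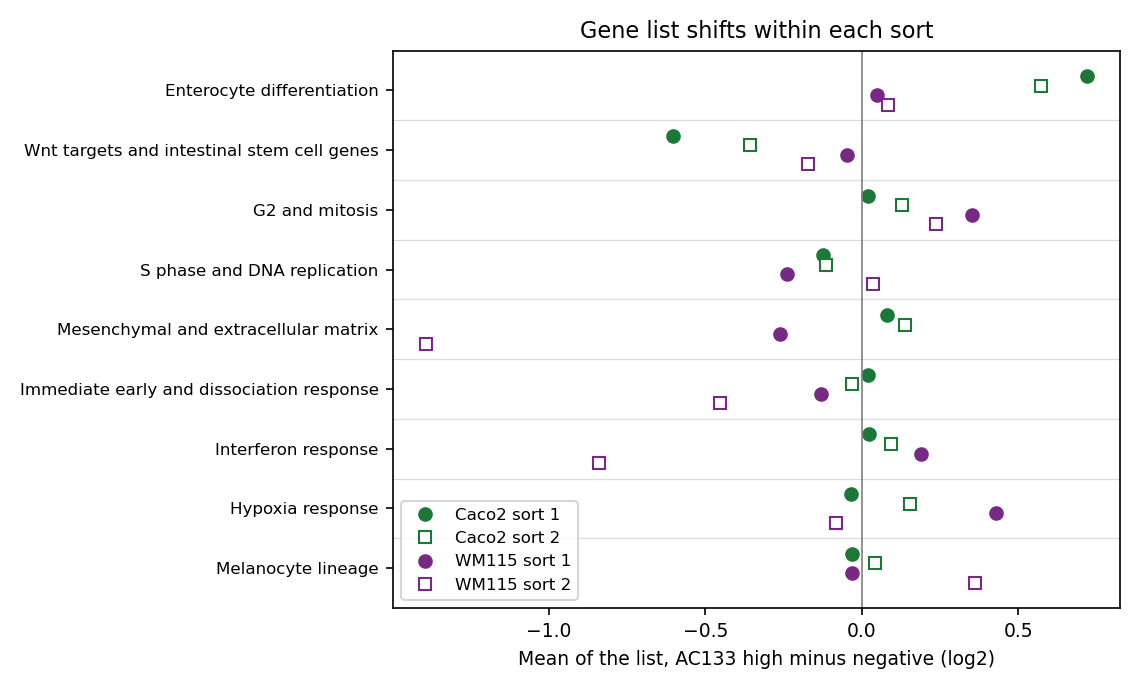
Mean log2 difference between AC133 high and negative cells over the genes of 9 lists within each sort, for Caco2 (green) and WM115 (purple), with sort 1 as filled circles and sort 2 as open squares. Enterocyte genes lie at 0.72 and 0.57 in the Caco2 sorts, genes of G2 and mitosis at 0.35 and 0.24 in the WM115 sorts, and mesenchymal genes at -0.26 and -1.39.

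The lists without a call in either line had small shifts. In Caco2 and WM115 respectively, p53 targets shifted by 0.03 and -0.08 log2 units, pluripotency genes by 0.09 and -0.01, unfolded protein and amino acid stress genes by -0.02 and -0.05, cholesterol synthesis genes by 0.11 and 0.05, ribosomal protein genes by -0.07 and -0.02, oxidative phosphorylation genes by -0.11 and -0.00, protein glycosylation genes by 0.08 and -0.02, and blood cell markers by -0.15 and 0.06. Enterocyte genes shifted by 0.07 in WM115, Wnt and stem cell genes by -0.11 with a median of 0.01, epithelial junction genes by -0.02, and tumour-initiating markers by 0.15 with a median of -0.04. In Caco2, melanocyte genes shifted by 0.01, immediate early genes by -0.00, hypoxia genes by 0.06 and interferon response genes by 0.06. The smallest adjusted p among these was 0.066, for oxidative phosphorylation in Caco2.

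The average over both lines asked which transcripts move the same way in both. EPHA4, an ephrin receptor, rose by 1.33 log2 units (SE 0.16), with 1.31 in Caco2 and 1.34 in WM115 and differences of 1.18 to 1.44 in the 4 sorts (adjusted p 0.039), a call lost under 10 of 16 alternatives. PROM1 rose by 3.89. SPTSSB, at least 2.02-fold, SCGN at 0.98, SLC3A1, an amino acid transporter subunit, at 0.98, HABP2, a serine protease, at 0.93 and MEP1A at 0.86 also passed with 1 direction in all sorts, but these 5 were detected on no WM115 array, and their averages rest on Caco2. Paired by sort, SCGN, SLC3A1, HABP2 and MEP1A missed the threshold, with adjusted p of 0.067, 0.068, 0.068 and 0.097, and they lost their calls under 8, 11, 9 and 11 of 15 alternatives. No gene that fell in all 4 sorts passed. GPR83, detected on no WM115 array, at -1.50 (adjusted p 0.093), CAMK2N1 at -1.06 (0.096), SH3BGRL3 at -0.70 (0.116), S100A4 at -1.86 (0.139) and ZCCHC24 at -0.79 (0.142) came nearest. MELK differed by 0.19 (adjusted p 0.851). In all 13 probes passed, 10 higher and 3 lower, against 8 in a fit paired by sort, 7 of them shared. With 1 array left out the count was 3 to 8, except for 17 without the Caco2 negative array of sort 2 and 177 without the WM115 negative array of sort 1.

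Of the lists, 7 passed in the average at the preset correlation, and none with an estimated one. Enterocyte genes rose by 0.36 log2 units and genes of G2 and mitosis by 0.18, while Wnt and stem cell genes fell by 0.29, mesenchymal genes by 0.36, histones by 0.17, immediate early genes by 0.15 and S phase genes by 0.11. Some of these averages rest on 1 line: mesenchymal genes shifted by 0.11 in Caco2 and -0.83 in WM115, enterocyte genes by 0.65 and 0.07, immediate early genes by -0.00 and -0.29, Wnt and stem cell genes by -0.48 and -0.11, and genes of G2 and mitosis by 0.07 and 0.29. With an estimated correlation the camera p was 0.015 for enterocyte genes, 0.070 for G2 and mitosis and 0.187 for Wnt and stem cell genes. It was 0.252 for mesenchymal genes, 0.256 for histones, 0.084 for immediate early genes and 0.324 for S phase, and none passed after adjustment. Without the WM115 negative array of sort 2 the mesenchymal shift was -0.05 and the call was lost, as were those of histones and immediate early genes, at -0.09 each. Without that of sort 1 the mesenchymal shift was -0.66. The histone call was also lost, at -0.07, without the Caco2 negative array of sort 2, and the shift was -0.27 without that of sort 1. The call of immediate early genes was also lost without the Caco2 high array of sort 1, at -0.12, and without the Caco2 negative array of sort 2, at -0.11. The S phase call was lost, at -0.02, without the WM115 high array of sort 1, and the shift was -0.20 without that of sort 2. Over probes detected on all 8 arrays the calls of Wnt and stem cell genes, at -0.067 (adjusted p 0.816), and of histones, at -0.17 (0.070), were lost.

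The difference between lines was tested itself. CD36 was 4.01 log2 units further toward the high cells in Caco2 than in WM115, AFP 3.31, ALB 3.08, VCAN 2.75 and SPTSSB 2.69, and EDN3 differed the other way, by -2.81. Limma called 9 probes, 8 higher and 1 lower, with adjusted p of 0.013 for CD36 and ALB, 0.021 for AFP and 0.034 for EDN3. The called probes of CD36 were detected on no Caco2 array, and those of EDN3, AFP and SPTSSB on no WM115 array, so these differences rest on 1 line. Paired by sort the count was 4, all shared, and SPTSSB, VCAN and EDN3 missed the threshold, with adjusted p of 0.053, 0.070 and 0.070, as did the other called genes SCGN and HABP2, with 0.078 and 0.107. EDN3 lost its call under 11 of 15 alternatives, VCAN under 8 of 15, and AFP, ALB and SPTSSB under 7 of 15. With 1 array left out the count was 0 to 5, except for 14 without the Caco2 negative array of sort 2 and 153 without the WM115 negative array of sort 1.

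Lists whose shift differed between the lines at the preset correlation were enterocyte genes by 0.58, mesenchymal genes by 0.94, Wnt and stem cell genes by -0.37, and immediate early genes by 0.29, besides G2 and mitosis. With an estimated correlation each lost its call, with adjusted p of 0.372, 0.563, 0.719 and 0.563 in that order. The mesenchymal difference was 0.32 without the WM115 negative array of sort 2 and 1.55 without that of sort 1. The Wnt and stem cell difference lost its call, at -0.18, without the Caco2 negative array of sort 1, and was -0.57 without that of sort 2. That of immediate early genes lost its call without the WM115 negative array of sort 2, at 0.17, the Caco2 negative array of sort 1, at 0.21, the Caco2 high array of sort 2, at 0.24, or the WM115 high array of sort 2, at 0.25. Over probes detected on all 8 arrays the calls of enterocyte genes, at 0.39 over 3 members, and of Wnt and stem cell genes, at -0.047 over 7, were lost. Without a filter on dim probes that of immediate early genes was lost, at 0.25 (adjusted p 0.100).

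The lines themselves were compared last. APOA1, an intestinal and hepatic apolipoprotein, was at least 220-fold higher in Caco2, and CDH17, an intestinal cadherin, at least 104-fold. GPNMB and PMEL, melanosome proteins, were higher in WM115, at least 140-fold and 159-fold. PROM1 was 1.18 log2 units and MELK 0.58 log2 units higher in Caco2, with adjusted p of 2.0e-04 and 0.0027. These values weigh the sorted high and negative cells equally. Unsorted cells were not measured, so the PROM1 value depends on the gates and is no level of the whole line. Limma called 8128 probes, 4091 higher in Caco2 and 4037 higher in WM115. The lines were cultured in different media, so line and medium are not separated.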

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

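Every test of an explanation here was chosen after the result it explains was seen, except the counts over other splits of the samples. The bound for liver-cell RNA was set before that test was run.

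The WM115 AC133 negative array of sort 2 had 175 probes more than 2-fold above and 37 more than 2-fold below each of the other 3 WM115 arrays. Poor hybridization is argued against by the 59.3% of probes detected on it, above the 55.5% to 58.6% of the other 3. RNA of Caco2 cells is argued against as well, since 50 abundant Caco2 probes rose by a median of 0.010 log2 units where the share needed, 42.1%, predicts 4.68 (SD 0.75). Fibroblasts in this sort may have contributed and cannot be told apart from a change in the cells: COL1A1 rose by 3.84 log2 units, COL3A1 by 0.60, FAP by 0.68 and PDGFRB by 0.62, but COL1A2, THY1 and POSTN were not above background, and the negative gate would not remove such cells. LUM, which rose by 0.80, and DCN of that list of 9 genes were detected on the other WM115 arrays too. The DCN probes differed by 0.28, -0.12 and -0.081, the last not above background. No biological explanation was tested, since the design separates nothing else between the sorts.

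Genes of liver plasma proteins and of enterocytes rose in the AC133 high Caco2 cells, led by AFP, ALB and FGB. Background correction and quantile normalization are each argued against as the whole cause. The smaller of the list means, 0.65 log2 units, was 0.55 without the correction and 0.63 with median scaling (SE over genes 0.10 and 0.12). Of the 14 members called, 12 and 9 kept their calls. Their median difference was 1.64 before, 1.18 without the correction and 1.53 with median scaling. The median SE of a single member was 0.16, 0.16 and 0.22 in that order. RNA of liver cells stays open. The 5 measurable genes of hepatocyte metabolism had a median difference of -0.073 (SE over genes 0.44), under the 1 log2 unit set beforehand as a bound. Their median signal of 5.07 lies near the 4.46 of undetected probes, with TDO2 at 1.19 and CPS1 at -0.88. Of 26 such genes on the array, 4 were detected on both high arrays and also 4 on both negative arrays. Liver plasma protein genes dimmer than ALB in the negative cells, where ALB had a log2 signal of 5.86, went both ways. HABP2, FGL1, HPX and ORM2 rose by 1.79, 1.63, 1.31 and 1.27, and C4BPA, C5 and KNG1 differed by 0.94, 0.84 and 0.69. SERPINA6, F7, F5, ORM1, ITIH2, SERPING1, A2M and HP lay between 0.32 and -0.03, and LCAT at -0.54. Brighter members also went both ways, with FGB at 2.10 and AMBP at -0.47. The gate on the brightest 10% would remove liver cells without the epitope. A difference between the AC133 states of Caco2 cells and unequal shares of the reporter clones in the gates also stay open, and neither was tested.

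Genes of G2 and mitosis rose in the AC133 high WM115 cells by a mean of 0.29 log2 units. The array that stood apart is argued against as the carrier of this shift, which was 0.39 without it (adjusted p 1.8e-21), although with all arrays and an estimated correlation the adjusted p of the list was 0.353. A larger share of cycling cells in all phases is argued against by the S phase list, whose highest shift with each WM115 array left out in turn was 0.071, and whose lowest was -0.27, below the bound of 0.147. A gate on the brightest cells might select larger cells of G2 alike in both lines, and this stays open: the difference between lines of -0.22 had an adjusted p of 2.7e-04 at the preset correlation but 0.719 with an estimated correlation. The protocol removed doublets by scatter, and whether the epitope itself follows the cell cycle was not tested.

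Some results drew attention because the effect of the AC133 state differed between the lines in a test of that difference, given here as Caco2 minus WM115 on the log2 scale. The probes of CD36 differed by 4.01 and 3.03, AFP by 3.31, ALB by 3.08, VCAN by 2.75, SPTSSB by 2.69, SCGN by 1.88, HABP2 by 1.71 and EDN3 by -2.81. Paired by sort, both CD36 probes, AFP and ALB passed, and SPTSSB, VCAN, EDN3, SCGN and HABP2 did not, with adjusted p of 0.053, 0.070, 0.070, 0.078 and 0.107. Among lists, enterocyte genes differed by 0.58, mesenchymal genes by 0.94, immediate early genes by 0.29, Wnt and stem cell genes by -0.37 and genes of G2 and mitosis by -0.22. With an estimated correlation none of these 5 passed, with adjusted p from 0.372 to 0.719. With 1 array left out the mesenchymal difference was as low as 0.32 and as high as 1.55, without the WM115 negative arrays of sort 2 and sort 1, and the Wnt difference lost its call at -0.18 without the Caco2 negative array of sort 1 and was -0.57 without that of sort 2. The G2 and mitosis difference lost its call, at -0.14 and -0.13, without the negative array of sort 1 of either line, Caco2 first. That of immediate early genes lost it when any 1 of 4 arrays was left out, lowest at 0.17 without the WM115 negative array of sort 2. AFP, SPTSSB, SCGN, HABP2 and EDN3 were detected on no WM115 array, ALB on 1 of them, and CD36 on no Caco2 array, so these differences rest almost wholly on 1 line each.

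Other splits of the arrays were counted for both comparisons with 4 arrays a side. For the average over lines, 2 of 18 splits called as many probes as the real one, which called 13, and 18 splits are too few for a share under 0.05. The highest other split, with 29, set sort 1 against sort 2 in both lines, parted no pair of arrays from the same sort, and points to a structure of the samples by sort. Among the 8 splits that part all 4 pairs, as the real one does, the highest other count was 9. That split keeps the Caco2 grouping and reverses that of WM115, so it tests the difference between lines and gives no level of chance. The fit with the sort as replicate block called 8. For Caco2 against WM115, 1 of 35 splits, the real one, called as many as its 8302 probes in a fit of 2 groups, and the highest other called 0. Every other split mixes both lines on each side, so the line difference widens its spread and works against any call. These counts therefore give no level of chance.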

How the results depend on the processing

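All alternatives here were chosen before the data were examined, and the cause of a change was not tested unless its construction shows it. The Caco2 count of 107 was 83 without background correction, 82 with an offset of 50, 94 in the deposited values and 75 without a filter, and the average count fell to 6 and the difference count to 3 with the offset of 50. With median scaling the Caco2 count was 41, 40 of them shared, and S phase in WM115 lost its call at -0.071. Without a filter the difference count was 4, and S phase in Caco2 passed at -0.12 (adjusted p 0.040, range 0.040 to 0.963), as it did with the line's own 4 arrays. With probes detected on all 8 arrays the counts were 1 in Caco2, 1 in WM115, 1 in the average and 0 in the difference, where 25, 1, 2 and 0 of the called probes were still tested. With the line's own 4 arrays, and so few degrees of freedom, Caco2 had 1 call and WM115 0, and PROM1 in WM115 missed the threshold at 3.60. The plain test named in the methods gave 979 probes in Caco2 and 498 in WM115 at unadjusted p under 0.05, and 0 in each after adjustment, where limma gave 1059 and 642 unadjusted. The replicate block gave 56, 8 and 4 calls in Caco2, the average and the difference.

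With an estimated correlation every list called in Caco2, WM115, the average or the difference lost its call, with adjusted p from 0.173 to 0.916, among them S phase at -0.10 and G2 and mitosis at 0.29 in WM115. With the most variable probe S phase was -0.088 and lost its call. With each array left out in turn, the lone array of a group taken to vary like the other groups, counts ran from 8 to 80 in Caco2, from 3 to 249 in WM115 (249 without the negative array of sort 1), from 3 to 177 in the average and from 0 to 153 in the difference. The S phase shift ran from -0.15 to -0.088 in Caco2 and from -0.27 to 0.071 in WM115, and that of G2 and mitosis from -0.0080 to 0.16 in Caco2. In WM115 hypoxia genes ran from -0.13 to 0.47, melanocyte genes from -0.092 to 0.42 and interferon genes from -0.93 to 0.28. PROM1 kept its direction and call in all 17 alternatives in Caco2, between 3.78 and 4.38. The enterocyte shift in Caco2 kept its call in 16 of 18, from 0.50 to 0.79, and no named gene past the threshold in a main comparison reversed. Signal close to background limits SPTSSB, VCAN, EGFLAM and EDN3, whose folds are lower bounds, and ZAP70, CYP26A1, NOTUM and the CD36 probe that fell by 3.93, each detected on 1 of 2 high arrays. With the offset of 50, which shrinks dim signals by construction, Caco2 differences moved by over 1.5 times for SPTSSB to 1.69, VCAN to 1.11, EDN3 to -1.82, ZAP70 to -1.76, CYP26A1 to -0.77, NOTUM to -0.78 and MEP1A to 1.02, all still called. NOTUM lost its call under 5 of 16 alternatives.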

Other observations

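The list of liver plasma proteins and the overlap between lines described here were chosen after the results were seen, and the lists behind them were written down before these tests.

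A list of liver plasma proteins was written after AFP, ALB and FGB were seen, and it holds them. Of its 40 measured genes 36 had a positive difference in the AC133 high Caco2 cells, the mean was 0.68 log2 units, and 10 passed over all genes on the probe used, with HPX, the haem carrier hemopexin, at 1.31, ORM2, an acute phase protein, at 1.27 and F2, prothrombin, at 0.95. The list shares 0 genes with the enterocyte list. A hypothesis is that more liver genes than those called may be higher in these cells. The 29 members with no probe past the threshold had a mean of 0.30 log2 units (SE 0.090), but this decides nothing, since the list and the split follow from the same arrays and members just short of the threshold, such as CPN1 at 1.60 and TTR at 1.00, lift the mean.

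Some genes were higher in the AC133 high cells of both lines. At unadjusted p under 0.05 and without PROM1, 21 genes were higher in both, where 11.8 would be expected of independent lines, and 14 were lower in both, near the 10.4 expected. In opposite directions, 8 were higher in Caco2 and lower in WM115, where 12.1 would be expected, and 7 the other way, where 10.1 would be. Both lines share the spread estimated for a probe and genes are not independent replicates, so these counts are descriptive. Besides PROM1 and EPHA4, the shared higher genes held CEACAM1, at 1.73 log2 units in Caco2 and 1.23 in WM115. A second CEACAM1 probe gave 0.02 and 1.78. CPN1, of the liver plasma protein list, stood at 1.60 and 0.97. Others were CENPA, at 0.50 and 0.65, the semaphorin gene SEMA6A at 0.50 and 1.02, and the phosphodiesterase gene PDE5A at 0.98 and 0.57. Among the shared lower genes were CD44, at -0.88 and -0.68, and CAMK2N1, at -0.63 and -1.49. A second CD44 probe gave -0.39 and -0.42. Of the genes named here, PROM1 and EPHA4 passed in the average over lines, and the others had adjusted p there from 0.062 for CEACAM1 to 0.303 for CENPA. Across all 13844 probes the differences of the lines had a correlation of 0.055.

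On the WM115 AC133 negative array of sort 2, the genes furthest above the other 3 WM115 arrays included AXL, a receptor kinase, at 4.52 log2 units above their mean, HLA-B, an antigen presentation gene, 4.42, DKK1, a Wnt inhibitor, 3.92, and IRF1, an interferon-regulated factor, 3.83. Among those below were CEACAM1, an adhesion protein, at -2.05, APOD, an apolipoprotein, at -1.79, and RAB27A, a melanosome transport gene, at -1.43. Of the 175 probes above, 114 were brighter on this array than on any Caco2 array.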
